A study of Solanum lycopersicum with 12 samples.

How the data were processed

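Total RNA of whole tomato fruit was measured on 12 single-colour (Cy3) Agilent arrays, 3 for each combination of 2 cultivars and 2 stages. Per the file headers, the deposited scanner files come from Agilent Feature Extraction 10.7.3.1 and hold intensity values: the processed signal, background-subtracted and detrended within each array with low signals replaced by surrogates, and the mean spot brightness and local background as scanned. The same deposited files hold other values per the file headers, which are spot types and quality marks. The authors also deposited a table of values whose unit is a ratio, each array's processed signal divided by that array's 75th percentile over all spots, control spots included. The table does not state this, and it was found by dividing the table by the scanner files. It follows the spot number, and no column was left without a sample.

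Each array has 45220 spots, of which 43803 are not controls. They carry 43603 different probes of 60 bases for 33936 array genes, 50 of the probes with 5 spots each. On each array 73.0 to 80.5% of the spots were well above background, the 75th percentile of the processed signal was 1208.8 to 1746.4, no spot was saturated, and 5 to 23 spots were marked as non-uniform and 0 to 3 as population outliers. Gene names came from the array's own columns, updated through the RefSeq gene table of assembly SLM_r2.1. That table gave 987 genes for 2275 probes, 1489 matched by symbol, 782 by Entrez number and 4 by the description. Other probes kept the array's gene name or contig. No genome was at hand, so probes were not mapped again.

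The log2 processed signal minus the array's 75th percentile over non-control spots was averaged over the spots of a probe, without spots marked as outliers. Probes well above background on all 3 arrays of at least 1 group were tested. Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), without a block for the slide. The 5 comparisons were pink against mature green in wt and in rin, rin against wt at mature green and at pink, and the interaction, which is the stage change in rin minus that in wt. The Benjamini-Hochberg adjustment ran within each comparison, with a threshold of 0.05, and counts are of probes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe for each array gene. Camera at an estimated correlation and fry were run beside it, and all were adjusted over the lists within a comparison. An array gene is a matched gene or else the array's own gene name or contig. Several members of a list can thus stem from 1 gene or gene family. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

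The named genes follow a rule fixed before the data were examined. They are 27 ripening genes, the 10 largest rises and the 10 largest falls past the threshold in each comparison among probes matched to 1 named gene whose arrays do not overlap between the groups (not asked for the interaction), and 2 to 4 members of each list with the largest changes past the threshold. A gene is represented by its probe of highest mean signal. No other probe of a named gene passed the threshold in the opposite direction. CNR, PL and CRTISO had no tested probe. The lists cover ripening transcription factors, ethylene biosynthesis, ethylene perception and signalling, cell wall modification, carotenoid and isoprenoid pathway, photosystem and antenna, Calvin cycle and Rubisco, chlorophyll metabolism, aroma volatiles, sugar and starch, phenylpropanoid and flavonoid, heat shock, cytosolic ribosomal proteins, histones and cell cycle, pathogenesis related, auxin response, cuticle and epidermis, seed storage and late embryogenesis, and reported RIN-bound genes. Their patterns were fixed at the same time. Members the patterns missed were added, and false text matches removed, after reading the annotation columns and before any expression value was read. Lists for glycoalkaloids and vascular tissue were left out, since no probe matched the former and only false text matches the latter.

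The alternatives changed the background correction (normexp with an offset of 50), the normalization (quantile, median centring, the authors' ratios), the filter, the handling of marked spots, the slide (fixed or random block), the arrays in the fit, the variance moderation, the test (Welch or Student), the probes of a gene and the fold threshold, and left out each array in turn. Leaving out replicate 3 of every group and averaging rin mature green replicates 1 and 2 were added after the data were examined. The procedure was tested on simulated data in which 200 of 34796 probes were changed, 50 each by 1.5, 2, 4 and 8-fold. It recovered 2, 28, 62 and 88% of them for wt, 4, 52, 80 and 96% for rin, 6, 24, 68 and 100% at mature green, 2, 24, 66 and 88% at pink, and 0, 4, 38 and 76% for the interaction. Of 51 simulated lists of 30 genes, the 1 shifted by 1 log2 unit had an adjusted p of 1.12e-48 (camera), and 0 of the others passed. The simulated noise was independent between probes, while the estimated correlation within the real lists was 0.019 to 0.55. The simulated lists thus cannot show whether the preset correlation limits false list calls. Each probe simulation was 1 draw with few changed probes, so its shares are rough and do not cover a comparison where many probes change.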

Results

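Gene expression was measured in whole tomato fruit of 2 cultivars. PK331 ripens normally (wild type, wt), and PK353 carries the ripening inhibitor mutation (rin), which keeps fruit from ripening. Fruit was picked at mature green, the stage before ripening, and at pink. Pink wt fruit was timed in days after breaker, the start of colouring. Fruit of rin does not turn pink, so its later harvest was timed in days after the first yellowing of the skin, with a different day count. Each of the 4 groups had 3 arrays, which the series calls biological replicates. The titles of the third rin samples at both stages say replicate 3, while the code in their descriptions ends in 1, so which rin fruit they come from is not certain, and the titles were followed. The 12 arrays measured RNA of the whole fruit, seeds included. On each array 73.0 to 80.5% of the spots lay well above background, and the small number of arrays limits the precision of every value. Genotype and cultivar are the same split here, so each difference between rin and wt is a difference between these 2 cultivars. At pink, and where the stage changes are compared, a difference in fruit age cannot be told apart from it. Each of the 3 slides held 1 array of every group, always at the same position, so position on the slide and group cannot be told apart. Where a gene's log2 change is first given for a comparison, its standard error from the limma fit follows, with 3 arrays in each group. Values within slides, in other settings or repeated later carry none. A change past the threshold has a Benjamini-Hochberg adjusted p under 0.05. Counts of list members are to be read against the share of all tested probes past the threshold. That share was 49% for the stage change in wt and 19.6% in rin, 4.5% at mature green, 31.8% at pink and 14.3% for the interaction. A fold given as at least a value is a bound, computed where a probe was well above background on none of the 3 arrays of 1 group, with that group set to the lowest level counted as well above background on each array or to its own signal where that was higher. These bounds and the log2 values hold for the processed signal. Normexp background correction adds an offset of 50, which by construction shrinks the changes of dim probes. Where it moves a printed gene change or list median that is past the threshold by over 1.5 times, its result is given at that comparison.

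Arrays of one group correlated at r = 0.957 to 0.996 across probes. The first principal component held 60% of the variance and ran from mature green to pink wt fruit. Pink wt arrays scored 193.1 to 201.5 on it, and mature green arrays of both cultivars scored −141.8 to −92.5. The rin pink arrays lay between, at 20.3 and 24.6 for replicates 1 and 2 and 86.7 for replicate 3, which stood apart from them. In every group replicate 3 was the array farthest from the other 2. In mature green wt the SD of the log2 difference was 0.567 between replicates 1 and 2, against 0.858 and 0.723 for the pairs with replicate 3. It was 0.459 against 0.688 and 0.626 in pink wt. In rin it was 0.253 against 0.647 and 0.642 at mature green, and 0.595 against 0.878 and 0.877 at pink. Rin mature green replicates 1 and 2 were the closest pair, with r = 0.996 and an SD of the log2 difference of 0.253, against 0.459 to 0.878 for other pairs within a group. Over the 36 probes spotted repeatedly that both measured, the difference of these 2 arrays had 6.0 times the variance that spot noise gives, against 35.4 to 298.5 times for the other pairs. They were counted as 2 samples, as labelled. Spot noise leaves out labelling and hybridization, so this value does not show whether they are separate fruit. With the 2 averaged into 1 sample, the probes past the threshold numbered 3911 instead of 6831 for the stage change in rin, 982 instead of 1581 at mature green and 3176 instead of 4983 for the interaction.

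**Figure D1:**
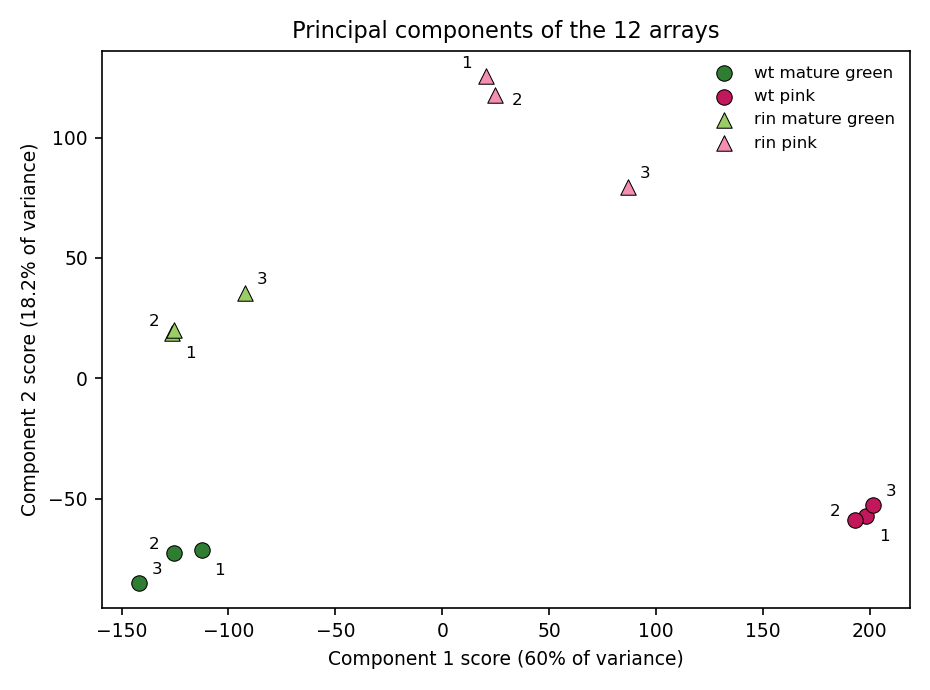
Scores of the 12 arrays on the first and second principal components of the normalized log2 signals, with colour for the group and the replicate number beside each point. Pink wt arrays lie apart on component 1 (193.1 to 201.5), and rin pink replicate 3 (86.7) lies nearer to them than rin pink replicates 1 and 2 (20.3 and 24.6).

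The first question was how expression changes as normal fruit ripens. In wt, from mature green to pink, PG2, the polygalacturonase that degrades pectin in ripe fruit, rose by 12.84 ± 0.84 on the log2 scale (adjusted p = 1.68e-06), and the endo-mannanase MAN4 rose at least 674-fold from a level that was not well above background in mature green fruit. ACS2, which makes the ethylene precursor in ripening fruit, rose by 9.98 ± 0.89, and the MADS-box regulator RIN, listed on the array as MADS-RIN, by 9.72 ± 1.03. The endoglucanase Cel2 rose by 8.0 ± 0.39, the lipoxygenase loxC, which feeds aldehyde volatiles, by 7.39 ± 0.73, the alcohol acyltransferase AAT, which forms esters, by 7.36 ± 0.94, and the first carotenoid enzyme Psy1 by 5.55 ± 0.35. The histidine decarboxylase gene hdc rose by 12.94 ± 2.28, the carbonic anhydrase gene ca3 at least 213-fold, and GA2ox2, which inactivates gibberellin, by 7.01 ± 0.87. Falls included the blue-light receptor PHOT2 at −6.87 ± 0.30, GP1, the polygalacturonase beta subunit, at −6.38 ± 0.46, the dihydroflavonol reductase DFR at least 38.9-fold and the ammonium transporter AMT1-3 at least 10.3-fold.

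Other ripening genes of wt rose as well. These were the ethylene synthesis genes ACS4 (6.52 ± 0.77) and ACO1 (6.19 ± 0.50), the expansin EXP1 (6.39 ± 0.58), E8 (5.27 ± 0.44), the chlorophyll-breakdown regulator SGR1 (5.02 ± 0.35), the galactosidase TBG4 (4.06 ± 0.49), the regulators AP2a (3.97 ± 0.27), FUL1 (3.43 ± 0.30) and NOR (3.23 ± 0.35), the ethylene receptors Never-ripe (3.84 ± 0.35) and ETR4 (2.94 ± 0.42), and ADH2 (1.75 ± 0.28). E4 rose by only 0.62 ± 0.16 and TAGL1 by 0.52 ± 0.15. HB-1 fell by 1.64 ± 0.22 and FUL2 fell by 0.51 ± 0.13. The probe matched to the beta-cyclase CYC-B, listed as NSY, changed by −0.08 ± 0.20 (adjusted p = 0.754).

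Of the 17 measured genes that earlier work reported as bound by RIN, 15 rose, 1 fell and 1 did not pass, as when adjusted over the list alone. Their median was 5.55 and the within-slide medians were 5.77, 5.74 and 5.36 (camera adjusted p = 4.96e-09, 6.73e-08 with slide as a block, adjusted p = 0.233 with an estimated correlation). The leading members were PG2, MAN4, ACS2 and RIN. These are also among the ripening genes named beforehand, so the list's values, here and in the other comparisons, are not evidence separate from those genes. Of the 44 photosystem and antenna genes 32 were lower and 2 higher, also adjusted over the list alone, among them the antenna gene CAB8 and a 1B antenna gene, listed only as contigs, at −4.41 ± 0.35 and at least 8.92-fold lower. Their median was −1.06, with −1.20, −1.21 and −0.97 within slides (camera adjusted p = 2e-06, blocked 6.56e-07, adjusted p = 0.332 with an estimated correlation). Of the 12 Calvin cycle and Rubisco genes 11 fell and none rose, the same 11 and 0 when adjusted over the list alone, with rbcS1, the small subunit of Rubisco, at −5.04 ± 0.28 and another small-subunit contig at −5.95 ± 0.29. The median was −2.72, with −2.33, −2.77 and −2.34 within slides (camera adjusted p = 5.92e-06, blocked 9.28e-06, adjusted p = 0.233 with an estimated correlation).

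Among 37 histone and cell cycle genes of wt 25 fell and none rose (26 and 1 adjusted over the list alone), with the cyclin CycD3;2 at least 52.9-fold lower, the cell cycle kinase CDKA1 at −3.95 ± 0.16 and the tubulin gene TUB at −3.19 ± 0.24. Their median was −1.37, with −1.32, −1.09 and −1.89 within slides and −0.77 with normexp correction (camera adjusted p = 3.84e-06, blocked 9.28e-06, adjusted p = 0.271 with an estimated correlation). Of 11 seed storage and late embryogenesis genes, which mark seeds in the fruit, 9 fell and none rose, also adjusted over the list alone, led by an 11S globulin contig at −6.49 ± 0.49 and another at −6.09 ± 0.37. The median was −3.49, with −3.40, −3.94 and −3.16 within slides (camera adjusted p = 2.49e-05, blocked 9.6e-05, adjusted p = 0.332 with an estimated correlation). Of 27 pathogenesis-related genes 15 rose and 3 fell, also adjusted over the list alone, with PR-1a1 at least 169-fold higher and an endochitinase contig at 5.6 ± 0.80. The median was 1.76, with 1.70, 2.42 and 1.24 within slides (camera adjusted p = 0.00124, blocked 0.000919, adjusted p = 0.349 with an estimated correlation), and it was 2.77 without wt pink replicate 3. Among 24 genes of ethylene perception and signalling 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Never-ripe, ERF1 at 2.99 ± 0.47 and EBF1, which turns over ethylene transcription factors, at 2.75 ± 0.25. The share of this list past the threshold was near the 49% of all tested probes. The median was 0.41, with 0.22, 0.69 and 0.36 within slides (camera adjusted p = 0.00353, blocked 0.0066, adjusted p = 0.349 with an estimated correlation), and it was 0.27 without wt green replicate 2.

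The remaining lists did not pass in wt, with camera adjusted p of 0.0615 or more. With normexp correction the carotenoid (adjusted p = 0.0296), ethylene biosynthesis (0.0459) and ripening transcription factor (0.0479) lists passed, with the test up, and with quantile normalization the ribosomal list (0.000946), with the test down. Higher and lower members numbered 8 and 5 of 16 for ethylene biosynthesis, 12 and 8 of 29 for the carotenoid and isoprenoid pathway, 18 and 34 of 69 for cell wall modification, 6 and 3 of 12 for ripening transcription factors, and 6 and 7 of 23 for aroma volatiles (median 0.01, mean −0.04). They numbered 14 and 18 of 49 for sugar and starch, 7 and 4 of 15 for phenylpropanoids and flavonoids, 6 and 5 of 33 for heat shock, and 2 and 3 of 8 for chlorophyll metabolism. For auxin response they were 2 and 11 of 27, for cytosolic ribosomal proteins 1 and 16 of 50, and for cuticle and epidermis 0 and 3 of 7. In these lists the starch synthesis gene AGP-S1 fell by 5.15 ± 0.56, the vacuolar invertase AI rose by 3.33 ± 0.57, the chalcone synthase CHS1, which starts flavonoid synthesis, rose by 3.60 ± 0.83, and the auxin-response repressors IAA11 and IAA7 were at least 44.8-fold and at least 42.0-fold lower.

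Of 34873 probes tested in wt, 17103 passed the threshold, 7496 higher and 9607 lower at pink, and 18329 passed with slide as a block. Of the 17103, 99.5% changed the same way within all 3 slides, as did all 91 named genes past the threshold, and all 91 passed with the block. Called probes were chosen on these same arrays, so such shares, here and below, are high through that choice and are no separate replication. With arrays centred on their medians 53.0% of the called probes were higher, against 43.8% here, so the majority direction depends on the scaling. The TAGL1 call ended without wt green replicate 3, wt pink replicate 1 or wt pink replicate 2, with changes of 0.45 to 0.63 over all 12 settings that leave out 1 array, and with quantile normalization (0.35, adjusted p = 0.0789). With normexp correction the wt changes were 4.91 for loxC, 7.51 for MAN4, 5.46 for ca3, 5.32 for PR-1a1, −3.48 for DFR, −1.96 for AMT1-3, −3.21 for IAA7, −3.90 for IAA11, −3.70 for CycD3;2 and −1.65 for the 1B antenna contig.

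The second question was what changes in rin from mature green to its later harvest. Some ripening genes rose there too. PG2 rose by 8.77 ± 0.84 (adjusted p = 0.000106), MAN4 at least 165-fold, and RIN itself by 6.13 ± 1.03. The RIN probe has no known position relative to the mutation here, so it checks little about the genotype. The neighbouring MADS-box gene MADS-MC, which acts in sepals and inflorescences, rose by 6.61 ± 1.10, AAT by 4.33 ± 0.94, SGR1 by 2.83 ± 0.35, NOR by 2.19 ± 0.35, E8 by 2.08 ± 0.44, Never-ripe by 2.01 ± 0.35 and FUL1 by 1.39 ± 0.30. ACS2, loxC, TBG4 and Psy1 passed more narrowly, at 2.98 ± 0.89 (adjusted p = 0.039), 2.63 ± 0.73 (adjusted p = 0.0291), 1.80 ± 0.49 (adjusted p = 0.0269) and 1.30 ± 0.35 (adjusted p = 0.0259). Cel2 fell by 2.08 ± 0.39 and FUL2 fell by 0.75 ± 0.13. EXP1 (0.06 ± 0.58), ACO1 (0.78 ± 0.50), ACS4 (2.17 ± 0.77), AP2a (0.81 ± 0.27), ETR4 (0.99 ± 0.42), ADH2 (0.52 ± 0.28), E4 (0.22 ± 0.16), TAGL1 (0.26 ± 0.15), HB-1 (−0.20 ± 0.22) and NSY (−0.04 ± 0.20) did not pass.

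Other rises in rin were the chloroplast heat shock gene HSP21 at 4.41 ± 0.86, the phosphate transporter PT1 at 3.02 ± 0.40 and TPS1, which makes trehalose phosphate, at 3.0 ± 0.50. The anthocyanin enzyme DFR was at least 18.8-fold lower, the expansin EXPA10 at least 22.6-fold, the mannanase MAN2 at least 6.43-fold and the monoterpene synthase MTS2 at least 5.61-fold. Reported RIN-bound genes were again higher, with 11 of 17 up and 1 down (12 and 1 adjusted over the list alone). Their median was 2.01, with 1.18, 1.84 and 1.78 within slides (camera adjusted p = 2.43e-06, blocked 1.09e-05, adjusted p = 0.297 with an estimated correlation). Seed storage genes fell, with 8 of 11 lower and none higher (9 and 0 adjusted over the list alone) and the 11S globulin contigs at −6.56 ± 0.49 and −5.58 ± 0.37. The median was −2.60, with −3.13, −2.04 and −2.64 within slides (camera adjusted p = 9.82e-07, blocked 1.09e-05, adjusted p = 0.297 with an estimated correlation). Histone and cell cycle genes fell, with 17 of 37 lower and none higher (20 and 0 adjusted over the list alone), CycD3;2 at −4.75 ± 0.26 and the cyclin CycA2 at −2.80 ± 0.41. The median was −0.80, with −0.75, −0.63 and −1.06 within slides (camera adjusted p = 8.39e-07, blocked 3.17e-06, adjusted p = 0.297 with an estimated correlation), and it was −0.51 without rin pink replicate 3.

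Cell wall genes of rin moved down more often than up, with 30 of 69 lower, 7 higher and 32 not past the threshold (35 lower and 10 higher adjusted over the list alone). Beside the rises of MAN4 and PG2, a polygalacturonase non-catalytic subunit contig fell by 5.16 ± 0.69. The median was −0.81, with −1.07, −0.70 and −0.89 within slides and −0.50 with normexp correction (camera adjusted p = 0.00334, blocked 0.00262, adjusted p = 0.297 with an estimated correlation). Calvin cycle and Rubisco genes fell in 5 of 12 cases with no rise (7 and 0 adjusted over the list alone), rbcS1 at −1.51 ± 0.28 and a small-subunit contig at −4.49 ± 0.51. The median was −0.76, with −1.07, −1.0 and −0.47 within slides (camera adjusted p = 0.00188, blocked 0.00147, adjusted p = 0.297 with an estimated correlation). Pathogenesis-related genes were lower in 9 of 27 cases and higher in none (10 and 0 adjusted over the list alone), with PR-5 at −3.32 ± 0.49. The median was −1.31, with −1.33, −1.53 and −1.60 within slides and −0.67 with normexp correction (camera adjusted p = 0.00874, blocked 0.0052, adjusted p = 0.401 with an estimated correlation). Heat shock genes were higher in 7 of 33 cases and lower in 1 (8 and 1 adjusted over the list alone), led by HSP21. The median was 1.13, with 1.37, 0.14 and 1.19 within slides (camera adjusted p = 0.00249, blocked 0.00482, adjusted p = 0.477 with an estimated correlation), and it was 0.68 without rin pink replicate 1 (adjusted p = 0.0247) and 0.71 without rin green replicate 3 (adjusted p = 0.0467).

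Smaller list shifts in rin were those of ethylene perception and signalling, where 5 of 24 rose and none fell, also adjusted over the list alone, with Never-ripe at 2.01 ± 0.35 and EBF1 at 1.05 ± 0.25. The median was 0.22, with 0.29, 0.24 and 0.27 within slides (camera adjusted p = 0.00762, blocked 0.0113, adjusted p = 0.386 with an estimated correlation), and its call ended with quantile normalization (adjusted p = 0.0673). Without rin green replicate 3 this median was 0.36. Cytosolic ribosomal protein genes fell in 6 of 50 cases and rose in none (2 and 0 adjusted over the list alone), a smaller share than the 19.6% of all tested probes. The median was −0.27, with −0.45, −0.27 and −0.05 within slides (camera adjusted p = 0.00398, blocked 0.00342, adjusted p = 0.477 with an estimated correlation), and the call ended without rin pink replicate 1 (adjusted p = 0.0903). Of 29 carotenoid and isoprenoid genes 4 rose and 3 fell, also adjusted over the list alone, with the lycopene cyclase CRTL-E-1 at −2.98 ± 0.35 and a second phytoene synthase record at 2.30 ± 0.45. The median was 0.33, with 0.16, 0.13 and 0.44 within slides (camera adjusted p = 0.0409, blocked 0.0329, adjusted p = 0.386 with an estimated correlation). That call ended without rin green replicate 2 (adjusted p = 0.055), rin green replicate 3 (0.0627) or rin pink replicate 3 (0.192, median 0.2), and with quantile normalization (0.13). The other lists did not pass in rin. In 2 of these the signs differed, chlorophyll metabolism with a median of −0.07 and a mean of 0.11 (test down) and phenylpropanoids with a median of 0.16 and a mean of −0.60 (test up). The nearest to passing was photosystem and antenna genes, with 6 of 44 lower and 2 higher (camera adjusted p = 0.0617). That list passed, with the test down, with slide as a block (adjusted p = 0.0255), with normexp correction (0.0413) and with quantile normalization (0.0025).

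Of 34874 probes tested in rin, 6831 passed, 2514 higher and 4317 lower at the later harvest, 7607 with slide as a block. Of the 6831, 99.2% changed the same way within all 3 slides, as did all 88 named genes past the threshold, of which 84 passed with the block. The block ended the calls of ACS2, EIL2 and a pair of class I small heat shock contigs. Without rin green replicate 1 or 2 the count was 3895 or 3891. Leaving out 1 array ended the ACS2 call in 7 of 12 settings (without wt green replicate 2, any wt pink array, rin green replicate 2 or 3, or rin pink replicate 3, with changes of 1.86 to 3.67), the loxC call without rin green replicate 1 or 2 or rin pink replicate 2 or 3 (2.04 to 3.33), the TBG4 call without rin green replicate 1 or 2 or rin pink replicate 3 (1.34 to 2.27), and the Psy1 call without rin green replicate 1 or 2 (0.88 to 1.52). With normexp correction the rin changes were 5.81 for MAN4, −1.37 for Cel2, −2.23 for DFR, −1.31 for MAN2, −2.26 for EXPA10, −1.04 for MTS2, −2.88 for CycD3;2, −0.83 for CycA2, −0.99 for PR-5, −1.62 for CRTL-E-1 and −1.96 for the Rubisco small-subunit contig.

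The stage changes of wt and rin, which share no array, correlated across probes at r = 0.72, with 0.576, 0.562 and 0.692 within slides. Probes are not independent replicates, so no test goes with this value. The changes had an SD of 1.76 in wt and 1.07 in rin. Of the probes higher in rin 73.4% were also higher in wt, and of those lower in rin 85.4% were also lower in wt. Together 1845 rose in both, against 540 for independent lists, 3688 fell in both, against 1189, and 70 and 74 moved oppositely. Cel2 was 1 of the genes with opposite changes. Without rin pink replicate 3, r was 0.625.

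**Figure D2:**
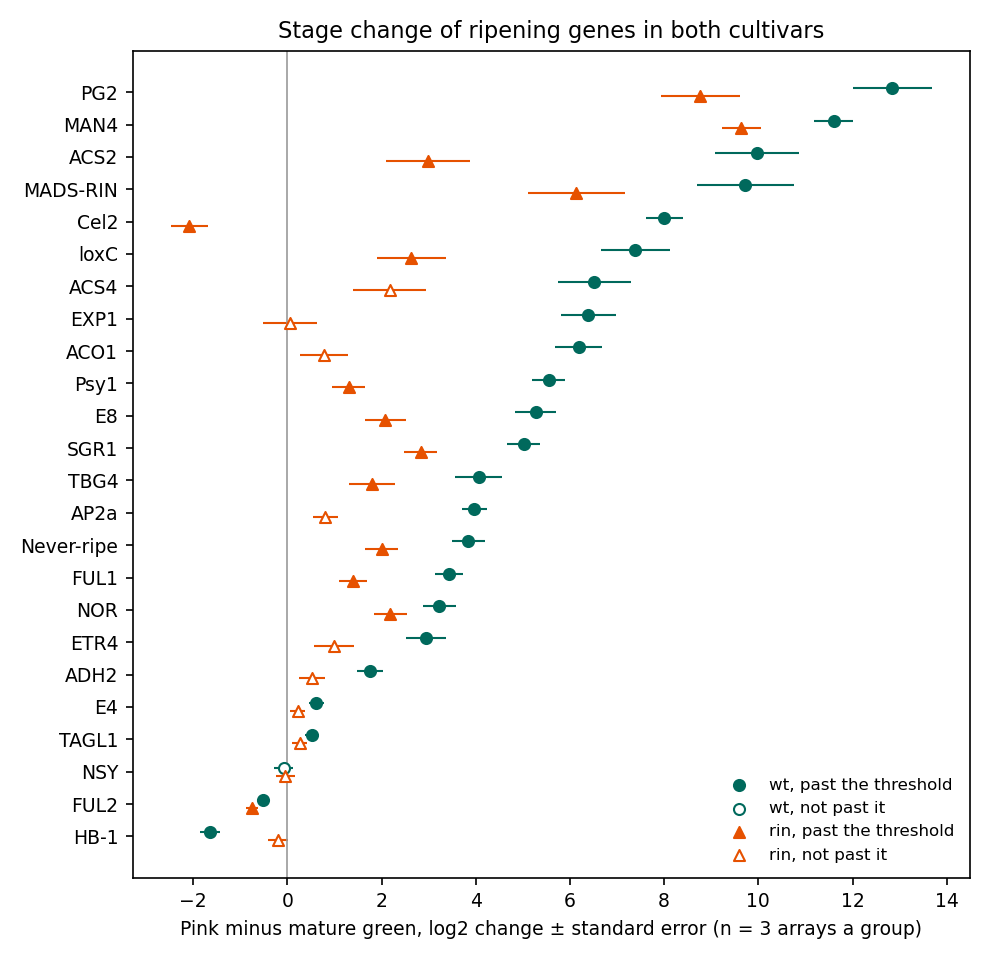
Log2 change from mature green to pink of the ripening genes fixed before the data were examined, with 1 standard error, in wt (circles) and rin (triangles), from 3 arrays in each group, filled where the change passed the threshold. PG2 rose by 12.84 in wt and 8.77 in rin, while Cel2 rose by 8.0 in wt and fell by 2.08 in rin. MAN4 was not well above background in mature green fruit of either cultivar, so its points rest on signal near background.

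The third comparison set the cultivars side by side before ripening. In mature green rin fruit PR-P2, a pathogenesis-related protein, was higher by 4.92 ± 0.69 (adjusted p = 0.00189), the glucanase gene Q`a by 4.72 ± 0.58, the subtilisin-like protease P69B by 4.92 ± 0.84, and the chitinase CHI3 by 3.67 ± 0.47. PR-5 was at least 3.5-fold higher. The wound-inducible invertase Wiv-1 was higher by 4.20 ± 0.71, the xylosidase XYL1 by 3.01 ± 0.48, ACO1 by 2.90 ± 0.50 and its relative EFE, another ethylene-forming enzyme, by 2.90 ± 0.52. AGL11, a MADS-box gene, was at least 245-fold lower in rin, and a chloroplast small heat shock contig at least 401-fold lower. Smaller differences down were those of the endoglucanase gene CELLULASE at −2.68 ± 0.43, the gene sumo at −2.33 ± 0.20 and the cell-wall invertase lin5 at −1.90 ± 0.33. E8 was higher by 2.05 ± 0.44 (adjusted p = 0.0235), a call that ended without wt green replicate 2, wt green replicate 3 or rin green replicate 3 (1.54 to 2.34). RIN (1.92 ± 1.03), ACS2 (0.33 ± 0.89), PG2 (−0.16 ± 0.84) and NOR (−0.49 ± 0.35) did not differ past the threshold.

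Among 27 pathogenesis-related genes 8 were higher in rin and 1 lower (16 and 1 adjusted over the list alone). Their median was 2.67, with 1.80, 2.78 and 3.28 within slides and 1.03 with normexp correction (camera adjusted p = 3.32e-09, blocked 2.75e-09, adjusted p = 0.156 with an estimated correlation). Of 27 auxin response genes only IAA7 differed, at −1.62 ± 0.36, and 2 were lower adjusted over the list alone. The list's median was −0.40, with −0.46, −0.25 and −0.06 within slides (camera adjusted p = 0.00088, blocked 0.000973, adjusted p = 0.137 with an estimated correlation), and it was −0.23 without wt green replicate 1. The IAA7 call ended without wt green replicate 1 or 2 or any rin green array (−1.86 to −1.31). Of 12 Calvin cycle and Rubisco genes 1, a Rubisco activase contig, was lower at −1.08 ± 0.17, and 4 were lower and none higher adjusted over the list alone. The median was −0.79, with −0.28, −0.79 and −0.96 within slides (camera adjusted p = 0.00129, blocked 0.00297, adjusted p = 0.425 with an estimated correlation). Of 69 cell wall genes 2 were higher and 1 lower, also adjusted over the list alone (median −0.20, within slides −0.23, −0.12 and −0.52, camera adjusted p = 0.0497, blocked 0.0392, adjusted p = 0.568 with an estimated correlation). Of 29 carotenoid genes none passed, nor adjusted over the list alone (median −0.13, within slides −0.07, −0.32 and −0.15, camera adjusted p = 0.0497, blocked 0.0451, adjusted p = 0.568 with an estimated correlation).

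The other lists did not pass at mature green (camera adjusted p of 0.093 or more). Among 16 ethylene biosynthesis genes 4 were higher and none lower, and among 17 reported RIN-bound genes 1 was higher and none lower. Heat shock genes had a median of 0.12 and a mean of −0.22 (test down), and the RIN-bound list, transcription factors, aroma, phenylpropanoid and sugar lists, with medians of −0.06, −0.03, −0.06, 0.22 and 0.03, also had a median, mean or test of differing sign. The cell wall list's call ended without wt green replicate 1 (adjusted p = 0.149), wt green replicate 2 (0.0893), rin green replicate 3 (0.209), rin pink replicate 1 (0.0526) or rin pink replicate 3 (0.0506), and with normexp correction (0.0719) or quantile normalization (0.131). Without wt green replicate 3 its median was −0.31. The carotenoid call ended without wt green replicate 2 (adjusted p = 0.224), wt pink replicate 1, 2 or 3 (0.056, 0.0551 and 0.0659), rin green replicate 2 or 3 (0.125 and 0.0611) or rin pink replicate 1 (0.0526), and with normexp correction (0.164) or quantile normalization (0.101).

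Of 34873 probes tested at mature green, 1581 passed, 984 higher and 597 lower in rin, 1787 with slide as a block. Of the 1581, 99.7% differed the same way within all 3 slides, as did all 37 named genes past the threshold, of which 32 passed with the block. The block ended the calls of mcpi, cMDH, MAN2, CDKB1 and MYB12. The count was 986 without rin green replicate 1 and 955 without rin green replicate 2. With normexp correction the differences were 1.53 for Wiv-1, 2.0 for XYL1, 0.94 for PR-5, −6.11 for AGL11 and −6.95 for the chloroplast small heat shock contig.

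At the pink stage the question was how fruit of rin differs from ripening wt fruit. In rin against wt, Cel2 differed by −11.00 ± 0.39 (adjusted p = 4.71e-08), hdc by −12.38 ± 2.28, ca3 by −9.04 ± 0.61, PR-1a1 by −7.28 ± 1.34, ACS2 by −6.67 ± 0.89, ACS4 by −5.39 ± 0.77, EXP1 by −4.64 ± 0.58, PG2 by −4.22 ± 0.84 and Psy1 by −3.95 ± 0.35. AP2a (−3.19 ± 0.27), TBG4 (−2.76 ± 0.49), ACO1 (−2.52 ± 0.50), Never-ripe (−2.29 ± 0.35), ETR4 (−2.24 ± 0.42), MAN4 (−1.92 ± 0.41), FUL1 (−1.90 ± 0.30) and NOR (−1.53 ± 0.35) were also lower, and E4 more narrowly (−0.48 ± 0.16, adjusted p = 0.0393). RIN (−1.67 ± 1.03), loxC (−2.08 ± 0.73), E8 (−1.14 ± 0.44), SGR1 (−0.96 ± 0.35), ADH2 (−0.65 ± 0.28), TAGL1 (−0.29 ± 0.15), FUL2 (0.22 ± 0.13) and NSY (0.01 ± 0.20) did not pass, and HB-1 was higher by 0.88 ± 0.22. MADS-MC was higher in rin by 5.42 ± 1.10, the gene ER5 by 4.59 ± 0.93, PHOT2 by 3.81 ± 0.30, the jasmonate synthesis gene AOS by 3.69 ± 0.84, the calcium pump LCA1 by 3.68 ± 0.44 and the antenna gene CAB6A by 3.63 ± 0.22. Asc-1, which gives resistance to a fungal toxin, was at least 5.59-fold higher. AGL11 was at least 29.0-fold and the chloroplast small heat shock contig at least 2100-fold lower.

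Of 17 reported RIN-bound genes 12 were lower in pink rin fruit and 1 higher (14 and 1 adjusted over the list alone). Their median was −2.08, with −2.91, −2.30 and −1.46 within slides (camera adjusted p = 1.8e-07, blocked 1.03e-06, adjusted p = 0.402 with an estimated correlation). Photosystem and antenna genes were higher in 23 of 44 cases and lower in 1, also adjusted over the list alone, with CAB6A and a CAB8 contig at 3.16 ± 0.35. The median was 0.84, with 0.95, 0.59 and 0.90 within slides (camera adjusted p = 1.13e-05, blocked 4.57e-06, adjusted p = 0.402 with an estimated correlation). Calvin cycle and Rubisco genes were higher in 6 of 12 cases and lower in none (7 and 0 adjusted over the list alone), with rbcS1 at 2.65 ± 0.28 and a small-subunit contig at 3.35 ± 0.29. The median was 0.97, with 1.48, 1.67 and 0.82 within slides (camera adjusted p = 0.00403, blocked 0.005, adjusted p = 0.402 with an estimated correlation). Histone and cell cycle genes were higher in 14 of 37 cases and lower in none, also adjusted over the list alone, with the mitotic kinase CDKB1 at 2.38 ± 0.25 and the cyclin CycB1 at 2.15 ± 0.39. The median was 0.70, with 0.48, 0.65 and 0.49 within slides and 0.37 with normexp correction (camera adjusted p = 0.00424, blocked 0.00688, adjusted p = 0.402 with an estimated correlation), and it was 0.43 without rin pink replicate 2.

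Of 29 carotenoid and isoprenoid genes 12 were lower in pink rin fruit and 5 higher, also adjusted over the list alone, with Psy1, the geranylgeranyl diphosphate synthase GGPS2 at −3.64 ± 0.52 and the entry enzyme DXS at −2.99 ± 0.31. The median was −0.16, with −0.55, −0.30 and 0.0 within slides and −0.26 with median centring (camera adjusted p = 0.0121, blocked 0.0173, adjusted p = 0.402 with an estimated correlation), and it was −0.36 without wt pink replicate 3. Of 24 ethylene perception genes 8 were lower and 2 higher (8 and 3 adjusted over the list alone), with ETR6 at −3.24 ± 0.54. The median was −0.18, with −0.27, −0.34 and −0.11 within slides and −0.28 with median centring (camera adjusted p = 0.0274, blocked 0.0434, adjusted p = 0.439 with an estimated correlation), and the call ended with quantile normalization (0.135). Pathogenesis-related genes were lower in 5 of 27 cases and higher in 1, also adjusted over the list alone, with PR-1a1 and the chitinase CHI14 at −3.22 ± 0.74. The share of this list past the threshold was smaller than the 31.8% of all tested probes. The median was −0.89, but it was −1.67, −0.98 and 0.15 within slides, so the direction turned on slide 3 (camera adjusted p = 0.0255, blocked 0.0241, adjusted p = 0.439 with an estimated correlation). That call ended without wt pink replicate 1 (adjusted p = 0.144, median −0.43) and with quantile normalization (0.0552). The other lists did not pass (camera adjusted p of 0.0629 or more), among them ripening transcription factors with 5 of 12 lower and 2 higher, which passed with normexp correction (adjusted p = 0.0497), and sugar and starch with 5 of 49 lower and 11 higher. Median, mean and test differed in sign for aroma volatiles, auxin response, cuticle and sugar, with medians of −0.06, 0.16, 0.06 and −0.01.

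Of 34873 probes tested at pink, 11086 passed, 6453 higher and 4633 lower in rin, 12227 with slide as a block. Of the 11086, 98.4% differed the same way within all 3 slides, as did 82 of the 83 named genes past the threshold (not AG1), and 80 passed with the block, which ended the calls of E4, AG1 and a vicilin record. The E4 call also ended in 8 of 12 settings that leave out 1 array (all but wt green replicate 1 or 3, rin green replicate 3 and rin pink replicate 3) and with quantile normalization (adjusted p = 0.069). With normexp correction the differences were −5.42 for ca3, −4.66 for PR-1a1, 1.16 for Asc-1, −2.66 for AGL11, −8.67 for the chloroplast small heat shock contig, 1.14 for CycB1 and −1.70 for CHI14. With arrays centred on their medians 48.4% of the called probes were higher in rin, against 58.2% here, so the majority direction depends on the scaling.

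**Figure D3:**
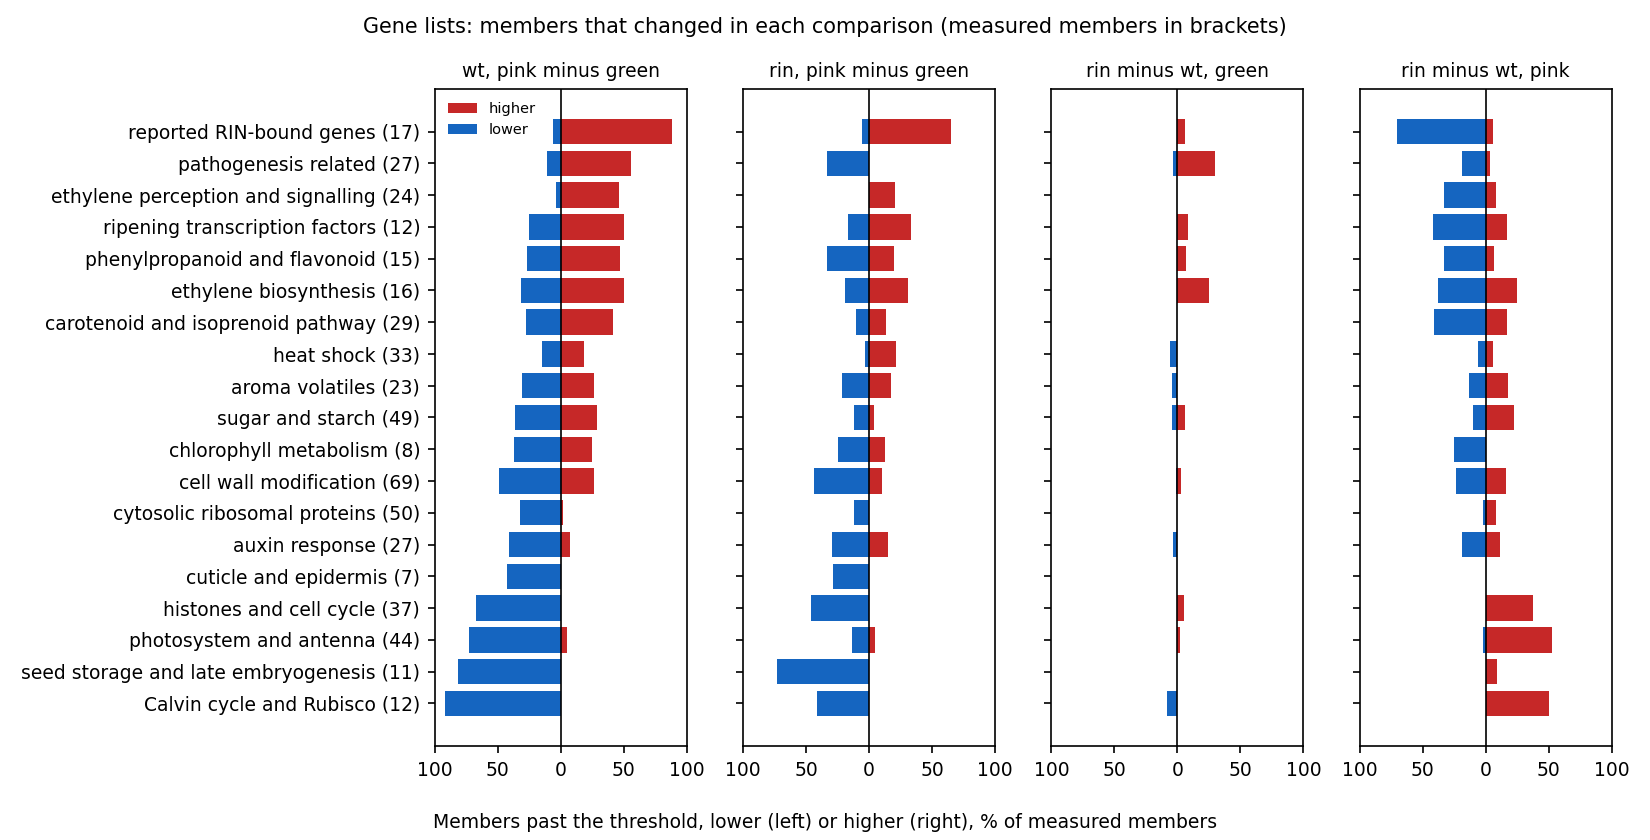
Share of each gene list's measured members that passed the threshold, higher to the right and lower to the left, in % of the members given in brackets, for 4 comparisons of 3 against 3 arrays. In wt 15 of 17 reported RIN-bound genes were higher at pink, and in pink fruit 23 of 44 photosystem and antenna genes were higher in rin than in wt. Of all tested probes 49, 19.6, 4.5 and 31.8% passed, in the order of the panels.

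The last comparison tested whether the stage change differs between rin and wt. It did for many ripening genes, as the difference rin minus wt in the stage change. Cel2 differed by −10.07 ± 0.55 (adjusted p = 1.56e-05), ACS2 by −7.00 ± 1.26, EXP1 by −6.34 ± 0.82, EFE by −5.98 ± 0.73, ACO1 by −5.42 ± 0.71, loxC by −4.76 ± 1.03, Psy1 by −4.25 ± 0.49, E8 by −3.19 ± 0.62, AP2a by −3.17 ± 0.38, SGR1 by −2.19 ± 0.49 and FUL1 by −2.04 ± 0.42. For HB-1 the difference was 1.44 ± 0.31. It was −4.35 ± 1.08 for ACS4, −4.06 ± 1.19 for PG2, −1.95 ± 0.58 for MAN4 and −1.83 ± 0.50 for Never-ripe, with adjusted p of 0.0245, 0.0461, 0.0484 and 0.0354. The MAN4 value is nominal, since MAN4 was not well above background in mature green fruit of either cultivar. RIN (−3.59 ± 1.45), NOR (−1.04 ± 0.50), TBG4 (−2.27 ± 0.69, adjusted p = 0.053) and ETR4 (−1.95 ± 0.59, adjusted p = 0.0511) did not pass, so their smaller rise in rin is not shown to differ from that in wt. INS-1P, which makes inositol phosphate, PHOT2, CAB6A and rbcS1 had positive differences of 4.80 ± 0.45, 4.28 ± 0.42, 4.03 ± 0.31 and 3.53 ± 0.40. MADS-MC differed by 5.38 ± 1.56 (adjusted p = 0.0436).

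Of 27 pathogenesis-related genes 12 had a lower and 1 a higher stage change in rin (17 and 1 adjusted over the list alone), with PR-P2 at −6.46 ± 0.97. The median difference was −3.63, with −4.34, −4.95 and −3.42 within slides and −2.09 with normexp correction (camera adjusted p = 8.01e-09, blocked 5.17e-09, adjusted p = 0.193 with an estimated correlation). Of 17 reported RIN-bound genes 11 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of −3.19 and −2.80, −2.61 and −2.93 within slides (camera adjusted p = 1.67e-08, blocked 1.73e-07, adjusted p = 0.193 with an estimated correlation). Photosystem and antenna genes had 14 of 44 members higher and none lower (16 and 0 adjusted over the list alone), with a median of 0.73 and 0.87, 0.79 and 0.97 within slides (camera adjusted p = 1.67e-08, blocked 5.17e-09, adjusted p = 0.26 with an estimated correlation). Calvin cycle and Rubisco genes had 6 of 12 higher and none lower (8 and 0 adjusted over the list alone), with a median of 1.92 and 1.53, 2.22 and 2.12 within slides (camera adjusted p = 5.57e-06, blocked 1.42e-05, adjusted p = 0.193 with an estimated correlation).

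Histone and cell cycle genes had 8 of 37 members with a higher and none with a lower stage change in rin (9 and 1 adjusted over the list alone), with TUB at 1.90 ± 0.34 and CDKA1 at 1.74 ± 0.23. The median was 0.37, with 0.28, 0.63 and 0.49 within slides (camera adjusted p = 0.0197, blocked 0.025, adjusted p = 0.482 with an estimated correlation), and the call ended without rin green replicate 3 (0.0633) or rin pink replicate 2 (0.0781, median 0.24). Of 16 ethylene biosynthesis genes 7 were lower and 2 higher (8 and 4 adjusted over the list alone), with ACS2, EFE and ACO1. The median was −1.71, with −1.73, −1.42 and −2.30 within slides (camera adjusted p = 0.0325, adjusted p = 0.397 with an estimated correlation). That call ended with slide as a block (adjusted p = 0.0681), with quantile normalization (0.0652), and without wt green replicate 3 (0.0543), wt pink replicate 1 (0.0814) or rin pink replicate 1 (0.0548). The other lists had camera adjusted p of 0.05 or more. With normexp correction ethylene perception (adjusted p = 0.0237), ripening transcription factors (0.0237), carotenoid (0.0283) and phenylpropanoid genes (0.0349) passed, with the test down. In the fit used here cell wall genes had 8 of 69 higher and 12 lower, with a median of 0.23 but a mean of −0.27 (test down), carotenoid genes a median of 0.0 and a mean of −0.43 (test down), and aroma volatiles a median of 0.02 with the test down.

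Of 34873 probes tested for the interaction, 4983 passed, 2813 higher and 2170 lower, 5867 with slide as a block, and 99.7% of the 4983 went the same way within all 3 slides. With arrays centred on their medians 49.5% of the called probes were higher, against 56.5% here, so the majority direction depends on the scaling. All 65 named genes past the threshold went the same way within all 3 slides, and the block ended the calls of PG2, MAN4 and MADS-MC. The count was 3256 without wt pink replicate 2, 3164 and 3192 without rin green replicate 1 and 2, and 7800 without rin pink replicate 3. Leaving out 1 array ended the calls of PG2 (kept without wt green replicate 1 or rin pink replicate 3, −5.0 to −3.29), MAN4 (kept without rin pink replicate 1 or 3, −2.42 to −1.40), Never-ripe (kept without rin pink replicate 3, −2.36 to −1.48) and MADS-MC (kept without wt green replicate 3 or rin green replicate 3, 4.56 to 6.97) in most settings, and that of ACS4 without wt green replicate 2, wt pink replicate 1 or 2, rin green replicate 3 or rin pink replicate 2 (−5.21 to −3.62). Quantile normalization ended the calls of PG2 (adjusted p = 0.0612), Never-ripe (0.0558), MAN4 (0.0662) and MADS-MC (0.0524), and normexp correction that of MAN4 (0.055). The loxC difference was −2.94 with normexp correction.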

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

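The slide and single-array tests of the pathogenesis-related list and the slide test of rin pink replicate 3 were chosen only after the result was seen.

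The stage change differed between the cultivars, by the interaction term of the limma fit, for 4983 probes. It differed for FUL1 (−2.04), AP2a (−3.17), HB-1 (1.44), ACS2 (−7.00), ACS4 (−4.35), ACO1 (−5.42), E8 (−3.19), PG2 (−4.06), EXP1 (−6.34), Cel2 (−10.07), Psy1 (−4.25), loxC (−4.76), SGR1 (−2.19), Never-ripe (−1.83) and MAN4 (−1.95, nominal, since it was not well above background in mature green fruit of either cultivar), of which PG2 and MAN4 did not pass with slide as a block. It also differed for 6 lists, with median differences of 1.92 for Calvin cycle and Rubisco, −1.71 for ethylene biosynthesis (not past the threshold with slide as a block, adjusted p = 0.0681), 0.37 for histones and cell cycle, −3.63 for pathogenesis-related genes, 0.73 for photosystem and antenna and −3.19 for reported RIN-bound genes. All 6 list calls were lost with an estimated correlation. Among the genes, leaving out 1 array ended the call of Never-ripe in 11 of 12 settings, those of PG2 and MAN4 in 10 each and that of ACS4 in 5. Quantile normalization ended the calls of PG2, MAN4 and Never-ripe.

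Splitting the 6 arrays of a comparison into 3 and 3 gives only 10 splits, too few for a share under 0.05. The real split was the 1 with the most probes in each of the 4 comparisons. It called 17065 probes in wt against at most 10 in another split, 6815 against 2 in rin, 1576 against 0 at mature green and 11062 against 2 at pink. Each other split mixes the 2 groups compared, so any difference between them widens the spread within both sides. The low counts of the other splits follow from this mixing and do not show whether chance gives such counts. For the interaction 2 of 100 drawn allocations of the 12 arrays gave as many probes, the real one with 4973 and another with 5832. Such allocations mix stages and cultivars, whose main effects widen the spread within most of them, so their low counts do not show whether chance gives such an interaction. That other allocation put all 3 wt pink arrays into 1 group against groups of mostly mature green and rin arrays, which is a structure of the samples.

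Pathogenesis-related genes had a median stage change of 1.76 in wt, with 15 of 27 higher and 3 lower, and of −1.31 in rin, with 9 of 27 lower, 18 not past the threshold and −0.67 with normexp correction. Both list calls were lost with an estimated correlation (adjusted p = 0.349 and 0.401), as was that of their difference (0.193). Over the 12 settings that leave out 1 array the median difference stayed at −4.12 to −3.27, which argues against a single array as its source. The highest adjusted p over these settings was 3.95e-07 (camera at the preset correlation). That value treats the genes as nearly independent, so it adds little on this point. The within-slide median differences were −4.34, −4.95 and −3.42. An effect shared alike by a slide's arrays cancels within each slide, so by the design it could not have made this difference. Position on the slide and group are the same split, so an effect of position, or of slide or scan that differs between groups, remains open. A difference between the cultivars, the mutation, or infection or wounding of some fruit could each have produced it, and none of these was tested. At pink the within-slide medians were −1.67, −0.98 and 0.15, and at mature green 1.80, 2.78 and 3.28.

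Rin pink replicate 3, whose title and description code differ in number, lay nearer to pink wt fruit (r = 0.933 to 0.936) than rin pink replicates 1 and 2 did (0.89 to 0.9). Admixture of wt RNA could raise ripening transcripts, and 582 ripening probes reached a median of 7.9% of the wt pink signal above replicates 1 and 2 (quartiles 2.3 and 20.5%), but 17 probes that mark the wt cultivar reached a median of 0.1% (quartiles 0 and 0.1%), far below the share a mixture needs. The deviations of this array correlated at most at 0.04 with those of another array of its slide, which argues against an effect that shifts the slide's arrays alike. A batch effect that differs between groups would not show in that value. Replicate 3 was the array farthest from the other 2 in every group. Deviations on slide 3 also correlated at 0.44 between both wt arrays and at 0.21 between wt pink and rin mature green. A batch of the replicate 3 samples therefore remains open. A difference in fruit age or in ripeness between samples remains open and was not tested. Without this array the interaction called 7800 probes against 4983, and the correlation of the stage changes was 0.625 against 0.72.

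The 1581 probes that differed between the cultivars at mature green could stem from a chromosome segment carried along with the mutation. Of 15 matched genes within 500 RefSeq genes of RIN 1 differed (6.7%), as against 60 of 890 others (6.7%, one-sided Fisher p = 0.652), but the upper end of the exact confidence interval for the 15 is 31.9%, so the bound set beforehand was too weak for so few genes and the segment remains open. Sequence differences under single probes could also contribute, and sister probes followed a called probe in 75.4% of pairs, against 96.2% in the wt stage change, a gap of 20.8 points that met the 20 points set beforehand. Following meant passing the same threshold, which 4.5% of all probes did at mature green and 49% in the wt stage change. A gap can thus arise without sequence differences, and it does not decide the question. Sisters went in the same direction in 95.8% of pairs, against 99.4%. A criterion added after the gap of 20.8 points was seen, following by at least 0.5 of the log2 change, gave 86.4 against 97.3%, a gap of 10.9 points, so cultivar and probe sequence cannot be told apart for the probes without a sister. In comparisons also chosen after the first gap was seen, the share following past the threshold was 89.8% between the cultivars at pink (a gap of 6.4 points), in the rin stage change 90.5% (5.7 points) and for the interaction 80.6% (15.6 points). A probe difference of fixed size on the log scale cancels in the interaction, so a lower share alone does not point to probe sequence. A difference in expression between the cultivars, or through the mutation, remains open and was not tested.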

How the results depend on the processing

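Leaving out replicate 3 of every group, averaging rin green replicates 1 and 2 and leaving out arrays for the lists and the correlation were chosen after the data were examined. The 17103 probes of wt were 9536 with Welch tests and 11130 with a 2-fold minimum. The 6831 of rin were 384 with Welch tests, 2811 with Student tests, 11341 without replicate 3 of every group and 3911 with rin green replicates 1 and 2 averaged. The 1581 at mature green were 96 (Welch), 578 (Student), 971 (only probes well above background on all 12 arrays, which drops probes off in 1 group), 2967 (without replicate 3) and 982 (averaged). The 11086 at pink were 487 (Welch), 4166 (Student) and 6937 (2-fold). The 4983 of the interaction were 9425 without replicate 3 and 3176 averaged. Welch and Student tests pool no spread across probes. Otherwise the cause was not tested. Leaving out 1 array gave 14676 to 18117 in wt, 3891 to 7271 in rin, 955 to 1983 at mature green, 8103 to 13046 at pink and 3164 to 7800 for the interaction. The correlation of stage changes, 0.72, was 0.625 to 0.747 without 1 array, 0.6 without replicate 3, and 0.686 to 0.728 with the other settings.

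Counts in the other settings, in the order wt, rin, mature green, pink and interaction, lay within 1.5 times. They were 17989, 7556, 1727, 10405 and 4373 with quantile normalization, 17741, 7094, 1586, 11081 and 5036 with median centring, 16856, 6678, 1701, 10375 and 5085 with normexp, and 17132, 6844, 1582, 11076 and 5001 with the authors' ratios. Median centring moved the median change from −0.049 to 0.096 in wt and from 0.095 to −0.011 at pink, and the split of calls from 7496 higher and 9607 lower to 9396 and 8345 in wt, from 6453 and 4633 to 5362 and 5719 at pink, and from 2813 and 2170 to 2491 and 2545 for the interaction. Normexp moved it at mature green from 984 and 597 to 887 and 814.

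Same-numbered arrays, which share a slide, correlated in their deviations above 0.1 in 9 of 18 pairs (−0.19 to 0.44), where pairing would need all 18. Still, 8 of 12 arrays correlated best with their own number, against 4 by chance, a hint from the data of a shared slide effect. With slide as a fixed replicate block the counts were 18329, 7607, 1787, 12227 and 5867, and as a random block 17970, 7690, 1942, 12103 and 6071. Of 414 named gene values 395 to 411 kept their side of the threshold under each of normexp, quantile, median centring, the authors' ratios and the block, and none past the threshold reversed. Of 95 list results 60 kept their side with an estimated correlation and 35, every call, lost it. The numbers were 93 with the block, 84 with normexp and 86 with quantile normalization. No called list reversed, while the test direction of 6 list results turned in at least 1 of these settings, all with adjusted p of 0.794 or more. Fry, which compares a list with no other genes, had an adjusted p of 0.05 or more for 6 of the 35 called, carotenoid (0.0865) and heat shock (0.153) in rin, Calvin cycle (0.104), carotenoid (0.347) and cell wall (0.349) at mature green, and pathogenesis-related at pink (0.157). Dim probes limit depth, as 29392 were well above background on all 12 arrays.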

Other observations

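The test of a joined RIN and MADS-MC transcript was chosen only after the result was seen.

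Some cultivar differences were present at both stages. Of the probes called in either stage 1012 were called at both, 585 higher in rin at both (182 for independent lists), 291 lower at both (79 for independent lists) and 136 in opposite directions. AGL11, a MADS-box gene, was at least 245-fold lower in rin at mature green and at least 29.0-fold lower at pink, and a chloroplast small heat shock contig at least 401-fold and at least 2100-fold lower. In all, 62 probes were well above background on all 6 wt arrays and on no rin array, and 89 were the reverse.

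MADS-MC lies beside RIN, and its probe rose by 6.61 in rin (8.47, 7.63 and 3.72 within slides), while RIN's probe rose by 6.13 (7.80, 6.88 and 3.71 within slides). In wt MADS-MC changed by 1.23 (adjusted p = 0.384) and RIN rose by 9.72. As a hypothesis, a transcript that joins the 2 genes in the mutant could carry both probes. The difference of the 2 stage changes in rin was 0.48, with 0.68, 0.75 and 0.01 within slides. Taken per array, since both probes lie on the same arrays, its standard error was 0.23 (95% interval −0.17 to 1.13, from 3 arrays in each group). It thus exceeded the 2 standard errors set as a bound, but that bound is too narrow for so few arrays and the interval holds 0, so the hypothesis stays open. Also, 2 separate transcripts that rise alike would give the same, and the positions of the probes relative to the mutation are not known here.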
